A study of Homo sapiens with 12 samples.

How the data were processed

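RNA was measured in INA-6, a human myeloma cell line whose growth depends on interleukin-6, after treatment with DMSO as the solvent control, with the Raf inhibitor SB590885 or with the MEK inhibitor PD325901. Per the labels' protocols, the cells grew in RPMI1640 with 10% fetal calf serum and 2 ng/ml interleukin-6, 300000 cells were treated, and 100 ng of total RNA was amplified and hybridised to Affymetrix HG-U133 Plus 2.0 arrays. Each of the 3 groups had 4 arrays, which the design text calls biological replicates, and p-values measure the spread between arrays. The concentrations of the inhibitors and the length of treatment are not given in the sources used here.

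The values are log2 expression values per probe set that the authors made with RMA, per the submitters' processing notes, which name R 3.0.1. Whether the 12 arrays were normalised together, and whether any filter was applied, is not given in the sources used here. The lowest value of each array lay between 5.85 and 6.01, and whether this compresses the fold changes of weakly expressed genes was not tested. Array medians lay between 6.88 and 6.97. No centring was added. No pair of arrays within a group held identical values for any gene.

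Of 54675 probe sets, 62 control probe sets were left out. The annotation used paired 41091 probe sets with 1 gene symbol, 1801 with several and 11721 with none, and only the first kind was named. Symbols were updated through the gene identifiers in the reference table. Each of the 19775 genes was represented by its probe set with the highest mean over the 12 arrays, and 10523 genes had more than 1 probe set. Some genes are not reported here. No coordinates were used.

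Groups were compared with limma 3.58.1 in R 4.3.3: a group-means model over all 12 arrays, which share 1 estimate of the spread, contrasts between groups, empirical Bayes moderation without trend, and Benjamini-Hochberg adjustment over the 19775 genes of each contrast. A gene was said to rise or fall at an adjusted p under 0.05. These choices, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Adjusted p-values of genes come from this limma fit with Benjamini-Hochberg adjustment throughout, and values after ± are SD over 4 arrays unless SE is written.

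Gene lists fixed in the same way, 35 in number, held 854 symbols, of which 787 were measured. They covered the RAF, MEK and ERK pathway and its outputs, other signalling and transcription programmes, cell cycle, metabolism, protein folding, plasma cell and myeloma genes, markers of other cell types and, as background, genes restricted to other tissues. They were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists of a contrast. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives. With an estimated correlation, 0 of 16 list calls for SB590885 against DMSO, 2 of 11 for PD325901 against DMSO (ERK pathway output and ERK feedback regulators, which share members) and 0 of 16 for SB590885 against PD325901 held. With the replicate number as a block as well, the feedback list passed (camera adjusted p = 0.0272) and the output list did not (camera adjusted p = 0.185). Members were counted over all genes, at an unadjusted p under 0.05, and adjusted over the list alone.

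Per comparison, the rule for named genes took the 12 largest rises and 12 largest falls among genes that passed the test, whose groups of 4 arrays did not overlap and whose higher group mean was at or above 6.92, the median over all probe sets. It added up to 4 members with the smallest p of each list discussed, the ERK pathway output list, and ARAF, MAP2K1, MAP2K2 and MYC. Of the list members, the alternatives were run for those that passed in lists that passed, a narrowing made after the data were seen. Gene families or members outside this rule are said to have been chosen after their values were seen.

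The labels number the arrays of each group 1 to 4, and a second label calls arrays 3 and 4 by the numbers 1 and 2 with an added R, whose meaning is not given in the sources used here. Deviations from the group means of same-numbered arrays of different groups correlated at 0.544 to 0.913 over 12 pairs, and 12 of 12 arrays had their best partner in another group at their own number, so the numbers were taken to pair the arrays. Arrays of another number correlated at 0.123 to 0.646 with the same R mark and at -0.718 to -0.443 with the other. Within the sets the pairing of the SB590885 arrays was weak: over all genes the difference of replicates 2 and 1 correlated at 0.86 between DMSO and PD325901, at 0.21 between SB590885 and DMSO, and at 0.19 between SB590885 and PD325901. For replicates 4 and 3 these correlations were 0.35, 0.067 and 0.10. The replicate block therefore acted on SB590885 largely through the R mark. The fit with the replicate number as a block, the fit with the R mark as a term, and fits within the arrays with and without the mark are given beside the counts they move.

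Other alternatives were all probe sets tested separately, the mean of a gene's probe sets, probe sets shared by several transcripts left out, low genes left out, moderation with trend or trend and robust, median centring, quantile normalisation, array weights, fits of 2 groups alone, arrays of the same second number as a random block or averaged, stricter thresholds, and each array left out in turn. After the data were seen, fits without the 3 arrays of replicate 2, fits within each set of arrays by R mark, and a correlation without shared arrays were added.

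Both inhibitors were compared with the same DMSO arrays. The values that unchanged groups would give against those arrays came from 100 simulated draws, and the DMSO arrays were also split 2 against 2. For each contrast the test was repeated on the 35 splits of the 8 arrays into groups of 4. Checks of explanations for patterns were written down with their predictions. For the histone and the replicate 2 patterns, 1 second test each was added after the first had been seen, and both results are printed. Exact permutation tests were two-sided.

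The fits were tested on simulated data for SB590885 against DMSO over 19775 genes, 200 of them changed, in 10 draws. Without a block, 16.2%, 66.6%, 96.2% and 99.4% of genes changed by 0.25, 0.5, 1 and 2 on the log2 scale were recovered, with 0.1 false calls per draw. With the block the shares were 57.2%, 96.0%, 100% and 99.4%, with 6 false calls per draw. The simulation gave all groups the same replicate effects and the residual spread of the block fit. The weak pairing of the SB590885 arrays was therefore not simulated, and these values do not test the block under it. A list shifted by 0.3 was called in 10 of 10 draws, and 0 of 340 tests of other lists were called. The noise of the simulated genes was drawn independently, so this does not test list calls where genes are correlated. The number of arrays limits the precision of every value.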

Results

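Expression was measured on 12 arrays of INA-6 myeloma cells, 4 each after DMSO, the Raf inhibitor SB590885 and the MEK inhibitor PD325901. Raf activates MEK, which activates ERK, so the design sets inhibition at 2 levels of 1 cascade beside the solvent. Neither doses nor treatment times are given in the sources used here, so differences between the compounds are differences between these treatments as applied. The first principal component held 46.7% of the variance and separated arrays 1 and 2 of every group from arrays 3 and 4, which carry the R mark. The second held 20.4% and separated SB590885 from the other arrays. Values of arrays without the mark had an SD of 1.54 ± 0.011 (n = 6) over probe sets, against 1.43 ± 0.026 (n = 6) with it (exact permutation test, two-sided p = 0.00216). This test permuted the 12 arrays freely, although same-numbered arrays were taken as pairs, so its p overstates the number of independent units. The 3' minus 5' difference of the GAPDH control probe sets, a sign of RNA quality, was 0.440 ± 0.035 with SB590885 and 0.425 ± 0.057 with PD325901, against 0.371 ± 0.033 with DMSO, and that of ACTB 1.65 ± 0.17 and 1.64 ± 0.10 against 1.58 ± 0.17 (n = 4 each). With SB590885 both were above the DMSO array of the same number in 4 of 4 pairs, and the part of such a difference in the changes below was not tested. Interferon response genes, which cells switch on after interferon, had a median of 11.2 on DMSO replicate 2 and 11.1 on PD325901 replicate 2, against 7.39 to 8.57 on the other 10 arrays.

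**Figure D1:**
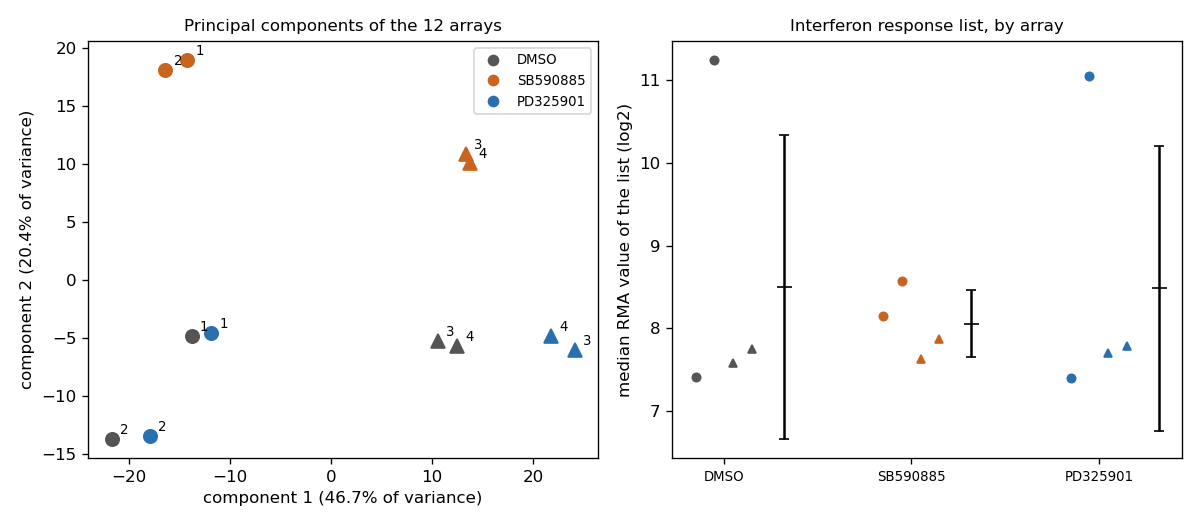
Left, the 12 arrays on the first and second principal components; right, the median RMA value (log2) of the 37 interferon response genes on each array, with mean ± SD of 4 arrays as bars. Circles are arrays without the R mark (replicates 1 and 2), triangles arrays with it (replicates 3 and 4), and colours are groups; DMSO and PD325901 replicate 2 stand at 11.2 and 11.1, the other arrays at 8.57 or lower.

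Comparing SB590885 with DMSO asks which genes respond when Raf is inhibited. Of 42 histone genes of the chromosomal clusters 18 rose, as did 6 of 20 targets of FOXO transcription factors and 9 of 29 genes of the amino acid response. Falls took in 3 of 10 ERK output genes, 11 of 35 ribosome biogenesis and other MYC target genes, 6 of 16 heat shock genes and 5 of 23 plasma cell genes. Each of these lists passed camera at the preset correlation and none did with an estimated correlation (adjusted p = 0.14 for heat shock genes to adjusted p = 0.245 for plasma cell genes), while the histone family was not a list. H2BC12, which encodes a histone H2B, rose from 11.04 ± 0.10 to 13.20 ± 0.36, a 4.47-fold difference (n = 4 each, adjusted p = 0.000206). CCL2, a chemokine that draws monocytes, fell from 9.20 ± 0.14 to 7.20 ± 0.56, a change of -2.00 on the log2 scale (adjusted p = 0.000883). ETV5, an ETS factor induced by ERK, fell from 8.73 ± 0.12 to 7.51 ± 0.07 (adjusted p = 6.18e-05).

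Among 19775 genes, 315 rose and 334 fell. Against these 649 genes the fit with the replicate block called 3742 (1797 higher, 1945 lower), with all 649 among them in the same direction, and the fit with the R mark as a term called 3331. Arrays without the mark alone gave 2637 (1290 higher, 1347 lower) and those with it 1066 (427 and 639), and all 649 differences had 1 sign in both sets. Centring each array on its median gave 142 higher and 239 lower, and quantile normalisation 869 higher and 763 lower. Changes of at least 1 on the log2 scale were 25 rises and 7 falls.

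The largest rise was that of LINC01419, a long noncoding RNA, at 2.36 (SE 0.20) on the log2 scale, and histone genes rose by 2.20 for H2BC12L, 2.16 for H2BC12, 2.07 for H2AC6, 1.94 for H2BC6, 1.82 for H2AC8, 1.64 for H1-10, 1.60 for H2BC9 and 1.51 for H2BC11. H2BC11 no longer passed without DMSO replicate 1 (adjusted p = 0.0522) or SB590885 replicate 2 (adjusted p = 0.0555). Histone genes of the chromosomal clusters, a family chosen after these values were seen, held 18 higher and 0 lower genes among 42, against 297 higher of the other 19733 genes. H2BC12L and H1-10 were not counted in this family and are among the other genes. The block gave 24 higher and 0 lower. Their median change was 0.27, and 0.26 with either quantile normalisation or median centring. Over the 35 histone probe sets ending in _at alone the median was 0.14, with 11 higher, and over the 13 whose names mark them as shared it was 0.80, with 8 higher. Many of these genes are near copies, so 1 probe set can read several of them.

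**Figure D2:**
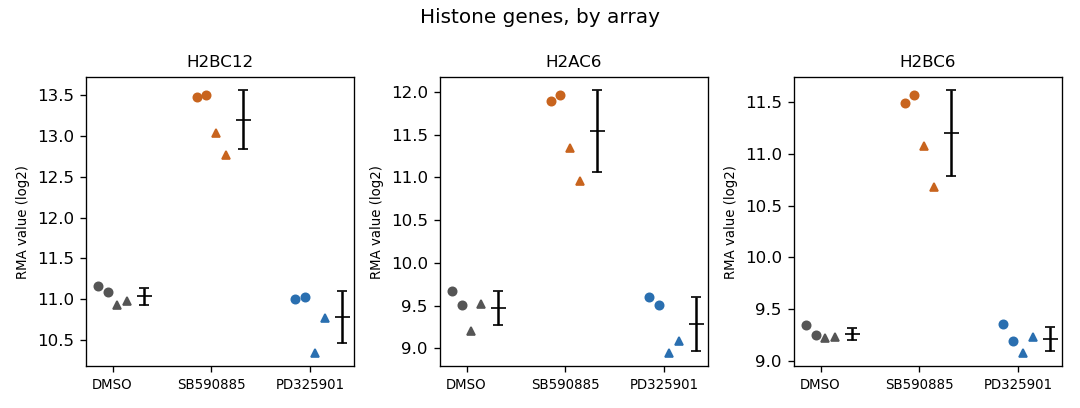
RMA values (log2) of H2BC12, H2AC6 and H2BC6 on each of the 12 arrays, with mean ± SD of 4 arrays as bars; circles are replicates 1 and 2 and triangles replicates 3 and 4, which carry the R mark. The SB590885 arrays lie above all DMSO and PD325901 arrays for each gene, with H2BC12 at 13.20 ± 0.36 against 11.04 ± 0.10 and 10.78 ± 0.32.

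ERK pathway output, a list of 10 transcripts that follow ERK activity, had 3 fallen, 0 risen and 7 not passing, with the same 3 adjusted over the list alone and with the block. It was lower as a list (mean -0.32, median -0.06, camera adjusted p = 0.000971, and adjusted p = 0.186 with an estimated correlation). ETV5 fell by 1.21, DUSP6 by 0.97 and DUSP4 by 0.92, the last pair encoding phosphatases that switch ERK off. The changes of ETV4 (-0.08), SPRY2 (-0.10), SPRY4 (0.02), PHLDA1 (0.11), CCND1 (-0.04), EPHA2 (0.04) and EPHA4 (-0.00) did not pass. SPRY2 (6.33) and EPHA2 (6.79) were under the median of all probe sets (6.92) with DMSO and SPRY4 (7.08) close to it, so these members say little about a fall. ERK feedback regulators, the proteins that restrain the cascade, held 5 fallen, 0 risen and 13 not passing (1 risen and 7 fallen adjusted over the list alone, 4 and 7 with the block). Camera gave an adjusted p of 0.0229 for this list, 0.174 with the block, 0.0739 with the R mark as a term, 0.0673 with centred arrays and 0.226 without SB590885 replicate 4, and adjusted p = 0.415 with an estimated correlation. SPRY1, another inhibitor of the cascade, fell by 0.46. DUSP7, also fallen, lost its call when any of 9 arrays was left out (highest adjusted p = 0.130). DUSP4, DUSP6, SPRY2 and SPRY4 are in both the output and the feedback list, so these lists do not give separate results. Of the immediate early genes, which respond within minutes to growth signals, 5 rose, 0 fell and 29 did not pass (7 risen adjusted over the list alone, 12 with the block; camera adjusted p = 0.000971, and adjusted p = 0.415 with an estimated correlation). JUND rose from 9.26 ± 0.33 to 11.16 ± 0.89 and passed except without DMSO replicate 1 (adjusted p = 0.0513). The other risen members, JUN, KLF2, PPP1R15A and ATF3, lost their calls without SB590885 replicate 1 (adjusted p = 0.0927, 0.0773, 0.132 and 0.135).

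FOXO targets had a median change of 0.31 (camera adjusted p = 2.73e-08, and adjusted p = 0.186 with an estimated correlation), with 6 risen, 0 fallen and 14 not passing. Adjusted over the list alone 9 rose, and with the block 14. TSC22D3, which encodes a glucocorticoid-induced leucine zipper, rose from 8.56 ± 0.13 to 10.00 ± 0.53 and CCNG2, a cyclin of arrested cells, by 1.29. CCNG2 lost its call without DMSO replicate 1 (adjusted p = 0.0527) or SB590885 replicate 2 (adjusted p = 0.0529). Without SB590885 replicate 2, BCL6 (adjusted p = 0.0690), SESN1 (adjusted p = 0.0656) and KLF2 (adjusted p = 0.0879) lost theirs too. The ATF4 and amino acid response list, which cells use when amino acids run short, rose by a median of 0.35 (camera adjusted p = 9.44e-11, and adjusted p = 0.228 with an estimated correlation), with 9 risen, 0 fallen and 20 not passing. Adjusted over the list alone 13 rose and 1 fell, and with the block 20 rose and 1 fell. SESN2, a stress-induced inhibitor of mTORC1, rose by 1.02 (SE 0.11), SLC7A11, the cystine transporter, by 1.01, CHAC1, which degrades glutathione, by 0.59, and PHGDH, the first enzyme of serine synthesis, by 0.40. Of the p53 targets 3 rose and 19 did not pass (4 risen adjusted over the list alone; 10 higher and 2 lower with the block), at a camera adjusted p of 0.00445, and adjusted p = 0.586 with an estimated correlation. TP53INP1, a p53-induced autophagy factor, rose by 0.88. SESN1, also in the FOXO list, and SESN2, also in the amino acid response list, were the other risen p53 targets.

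Ribosome biogenesis genes and other MYC targets fell by a median of 0.28 on the log2 scale, with 11 fallen, 0 risen and 24 not passing (24 fallen adjusted over the list alone and 24 with the block). The list had a camera adjusted p of 1.8e-18, and adjusted p = 0.186 with an estimated correlation. LYAR, a nucleolar protein, fell by 0.69, NOP16 by 0.60 and UTP20, of the small-subunit processome, by 0.53. MYC itself did not pass, at 12.24 ± 0.12 against 12.32 ± 0.17. Heat shock genes, chaperones and their helpers, had 6 fallen, 0 risen and 10 not passing (11 fallen adjusted over the list alone and 11 with the block). Their median was -0.34 (camera adjusted p = 5.36e-12, and adjusted p = 0.14 with an estimated correlation). HSPH1 fell by 0.93, FKBP4 by 0.70, HSPA4L by 0.66 and STIP1 by 0.58. The proteasome list was lower (median -0.15, camera adjusted p = 0.000158, and adjusted p = 0.618 with an estimated correlation) with 0 of 22 members passing, 4 lower at an unadjusted p under 0.05, 0 adjusted over the list alone and 7 lower with the block.

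Plasma cell identity genes, which mark antibody-secreting cells, had 5 fallen, 0 risen and 18 not passing (6 fallen adjusted over the list alone, 8 with the block; camera adjusted p = 1.47e-05, and adjusted p = 0.245 with an estimated correlation). FCRL5, a surface receptor of these cells, fell by 0.81, and SLAMF7, a surface protein targeted in myeloma, by 0.90 but not without DMSO replicate 1 (adjusted p = 0.0588). Without that array the fallen members XBP1 (adjusted p = 0.0985) and LAX1 (adjusted p = 0.0658) lost their calls too. Secreted cytokines and chemokines had 3 fallen and 24 not passing, also adjusted over the list alone (4 fallen with the block; camera adjusted p = 0.00359, and adjusted p = 0.245 with an estimated correlation). The fallen members included CCL2, IL16, a chemoattractant of CD4 cells, at -0.81, and IL10 at -0.31. IL16 did not pass with the mean of its probe sets (adjusted p = 0.0656), nor did the list with low genes left out (adjusted p = 0.127). Of 28 adhesion genes 3 fell, 4 adjusted over the list alone, and the block gave 10 lower and 1 higher (camera adjusted p = 0.0229, and adjusted p = 0.245 with an estimated correlation); they included ITGA4, an integrin alpha chain, at -0.85. The adhesion list did not pass with low genes left out (adjusted p = 0.0663) or arrays centred (adjusted p = 0.0520). Other large falls were those of SLA at -1.19, STS, the steroid sulfatase, at -1.45, TRAT1 at -1.06, SCN3A at -1.03 and KMO, of the kynurenine pathway, at -0.96. CD48, a surface glycoprotein of lymphocytes, fell by 1.52 and lost its call without DMSO replicate 1 (adjusted p = 0.0552) or 2 (adjusted p = 0.0525), or SB590885 replicate 1 (adjusted p = 0.057) or 2 (adjusted p = 0.0555).

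NF-kB targets were higher (median 0.07, camera adjusted p = 0.000971, and adjusted p = 0.186 with an estimated correlation), with 2 risen and 24 not passing (4 risen adjusted over the list alone, 9 with the block). RELB, an NF-kB subunit, rose by 0.59. Cholesterol synthesis genes were higher (median 0.14, camera adjusted p = 0.000769, and adjusted p = 0.522 with an estimated correlation) with 2 risen and 22 not passing. Adjusted over the list alone 6 rose and 2 fell, and with the block 8 and 2. The 2 risen genes, IDI1 and SREBF2, lost their calls without DMSO replicate 1 (adjusted p = 0.0874 and 0.0653). They also did so without DMSO replicate 2 (adjusted p = 0.0899 and 0.0561) or SB590885 replicate 2 (adjusted p = 0.0998 and 0.0555). The lysosome and autophagy list had 1 risen and 29 not passing (2 risen adjusted over the list alone; 9 higher and 2 lower with the block), with a camera adjusted p of 0.032, and adjusted p = 0.696 with an estimated correlation. Its call ended without SB590885 replicate 1 (adjusted p = 0.145) or 2 (adjusted p = 0.132), or DMSO replicate 3 (adjusted p = 0.0895) or 4 (adjusted p = 0.167). The risen gene, NEU1, lost its call when any of 8 arrays was left out (highest adjusted p = 0.133). The interferon response list was lower (median -0.51, camera adjusted p = 0.00162, and adjusted p = 0.812 with an estimated correlation) with 0 of 37 members passing in limma or adjusted over the list alone, 3 lower unadjusted, and 5 lower and 1 higher with the block. It no longer passed, with the direction turned, without DMSO replicate 2 (adjusted p = 0.896), and without all arrays of replicate 2 its adjusted p was 0.391.

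The other lists did not pass for SB590885 against DMSO. RAS, RAF, MEK and ERK components had a median of 0.02, PI3K, AKT and mTOR components 0.03, DNA replication and G1-S genes -0.01, mitosis genes 0.02, cyclin D and CDK inhibitor genes 0.08, BCL2 family genes 0.03, B cell genes -0.02, myeloma oncogenes and surface receptors -0.03, IL6-JAK-STAT3 genes 0.00 and oxidative phosphorylation genes -0.00. The unfolded protein response list had a median of -0.07 and a mean of 0.02, glycolysis and hypoxia genes 0.01 and -0.06, and receptor tyrosine kinases and ligands 0.01 and -0.04, so that median and mean differed in sign. Of 20 T and NK cell markers 2 fell, also adjusted over the list alone, with TRAT1 (-1.06) as the larger fall, at a list median of -0.03 and a mean of -0.09. Medians of markers of monocytes (0.02), fibroblasts (0.00), erythroid cells (0.01, with a mean of -0.03) and endothelium (-0.01), and tissue-restricted genes as background (0.01), stayed near 0. The pathway genes ARAF (0.05), MAP2K1 (-0.02) and MAP2K2 (0.09) did not pass.

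In fits without a block, the count of 649 genes moved when single arrays were left out. It was 245 without DMSO replicate 1, 288 without SB590885 replicate 1, 335 without DMSO replicate 2, 260 without SB590885 replicate 2, 387 without DMSO replicate 3 and 393 without DMSO replicate 4. Leaving out an array also unbalanced the R mark between groups, and its part in these counts was not separated.

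Comparing PD325901 with DMSO asks the same of MEK. Large falls were those of the ERK phosphatase gene DUSP6, CCL2, the immunoglobulin gene IGLC1, CD48, IL16, the feedback inhibitors SPRED2 and SPRED1 and the ETS factor ETV5. Of the ERK output list 3 of 10 genes fell, and of the ERK feedback list 5 of 18, with DUSP4 and DUSP6 in both counts. DUSP6 fell from 9.62 ± 0.27 to 6.97 ± 0.25, to 0.160 of the DMSO level (n = 4 each, adjusted p = 4.6e-06). SPRED2 fell from 8.75 ± 0.17 to 6.93 ± 0.07 and ETV5 from 8.73 ± 0.12 to 6.91 ± 0.14. With PD325901 these genes, CCL2 (6.60) and IL10 (6.43) were near or under the median of all probe sets (6.92), and tissue-restricted genes had a median of 6.67 on these arrays, so the sizes of their falls are not taken as exact. The rises were smaller, led by DEPTOR, an inhibitor of mTOR, at 1.03 (SE 0.14) and DCLK1, a kinase linked to microtubules, at 0.99 (SE 0.13).

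Of 19775 genes, 17 rose and 100 fell. The replicate block called 1610 (387 higher, 1223 lower), all 117 among them in the same direction, and the R mark as a term called 1289. Arrays without the mark gave 186 (73 higher, 113 lower) and those with it 1079 (112 and 967), with 1 sign in both sets for all 117. Quantile normalisation gave 175 higher and 176 lower, and centring each array on its median 9 and 84. Without DMSO replicate 2 the count was 72. Changes of at least 1 on the log2 scale were 1 rise and 20 falls.

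**Figure D3:**
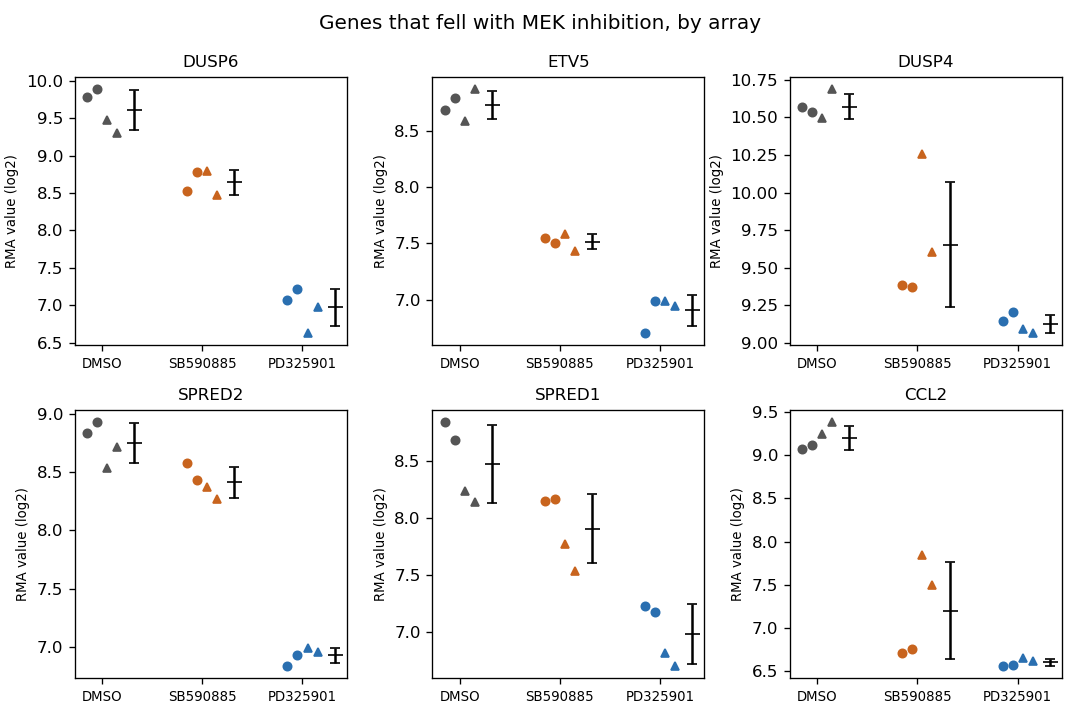
RMA values (log2) of DUSP6, ETV5, DUSP4, SPRED2, SPRED1 and CCL2 on each of the 12 arrays, with mean ± SD of 4 arrays as bars; circles are replicates 1 and 2 and triangles replicates 3 and 4, which carry the R mark. PD325901 arrays are lowest for DUSP6, at 6.97 ± 0.25 against 8.64 ± 0.17 with SB590885 and 9.62 ± 0.27 with DMSO.

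The ERK pathway output list had 3 fallen, 0 risen and 7 not passing (4 fallen adjusted over the list alone), a mean of -0.61 and a median of -0.10 (camera adjusted p = 1.93e-07, and adjusted p = 0.036 with an estimated correlation). In the fit with the block, camera with an estimated correlation gave adjusted p = 0.185. DUSP4 fell by 1.44. Changes of ETV4 (-0.15), SPRY2 (-0.03), SPRY4 (0.01), PHLDA1 (0.09), CCND1 (-0.12), EPHA2 (0.05) and EPHA4 (-0.07) did not pass. Of the ERK feedback regulators 5 fell, 0 rose and 13 did not pass (7 fallen adjusted over the list alone, 9 with the block; camera adjusted p = 9.55e-10, and adjusted p = 0.0413 with an estimated correlation). In the fit with the block, camera with an estimated correlation gave adjusted p = 0.0272 for these regulators. SPRED1, which restrains RAF activation, fell by 1.49. Secreted cytokines and chemokines had 4 fallen and 23 not passing, also adjusted over the list alone and with the block (camera adjusted p = 0.0011, and adjusted p = 0.407 with an estimated correlation), but not without PD325901 replicate 1 (adjusted p = 0.0968). CCL2 fell from 9.20 ± 0.14 to 6.60 ± 0.04, IL16 by 1.97 and IL10 by 0.34.

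IGLC1, whose probe set can read several lambda light chain genes, fell from 9.66 ± 0.54 to 7.64 ± 0.60 and CD48 from 11.82 ± 0.34 to 9.85 ± 0.72. SYPL1 fell by 1.44, the clock gene PER2 by 1.34 and PRKD2, a protein kinase D, by 1.28. CCNE1, the cyclin of entry into S phase, fell by 0.90 (SE 0.10). It was the 1 fallen gene among 41 of DNA replication and G1-S, also adjusted over the list alone, while the block gave 17 lower. The list's median was -0.16 (camera adjusted p = 5.7e-11, and adjusted p = 0.614 with an estimated correlation). Ribosome biogenesis and other MYC targets had a median of -0.18, with 1 fallen and 34 not passing (4 fallen adjusted over the list alone, 7 with the block; camera adjusted p = 2.06e-12, and adjusted p = 0.407 with an estimated correlation). The fallen gene, PA2G4, lost its call when any of 7 arrays was left out (highest adjusted p = 0.114). Heat shock genes had a median of -0.19 with 0 of 16 passing over all genes or adjusted over the list alone 4 lower unadjusted and 6 lower with the block (camera adjusted p = 0.000171, and adjusted p = 0.407 with an estimated correlation).

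Rises included EAF2, an elongation factor partner, at 0.76, FRZB, a secreted Wnt antagonist, at 0.51, the deubiquitinase gene USP2 at 0.50, FBXO16 at 0.49 and RABAC1 at 0.49. The unfolded protein response list, chaperones and factors of endoplasmic reticulum stress, was higher (median 0.23, camera adjusted p = 4.21e-11, and adjusted p = 0.614 with an estimated correlation) with 0 of 27 passing, 12 higher unadjusted, 4 risen adjusted over the list alone and 15 with the block. Plasma cell identity genes were higher (median 0.12, camera adjusted p = 0.00089, and adjusted p = 0.614 with an estimated correlation), with 1 risen and 22 not passing (2 risen adjusted over the list alone; 5 higher and 2 lower with the block), though not without PD325901 replicate 2 (adjusted p = 0.0682). The risen gene, CAV1, lost its call when any of 5 arrays was left out (highest adjusted p = 0.102).

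Calls of 3 further lists depended on single arrays. FOXO targets (median 0.03, 0 of 20 passing, 2 higher unadjusted, 3 with the block, camera adjusted p = 0.0326, and adjusted p = 0.815 with an estimated correlation) lost theirs without PD325901 replicate 1 (0.109) or 2 (0.185), or DMSO replicate 3 (0.108) or 4 (0.0959). Mitosis genes (median -0.08, 0 of 40 passing, 2 lower unadjusted, 3 with the block, camera adjusted p = 0.00945, and adjusted p = 0.85 with an estimated correlation) lost theirs without DMSO replicate 1 (0.0640) or 2 (0.317), or PD325901 replicate 3 (0.958) or 4 (0.103). Monocyte markers (median 0.04, 0 of 18 passing, 1 higher unadjusted, 0 with the block, camera adjusted p = 0.0187, and adjusted p = 0.815 with an estimated correlation) did so without DMSO replicate 1 (0.104) or 2 (0.146), or PD325901 replicate 3 (0.135) or 4 (0.126). Mitosis genes also lost the call with low genes left out (0.125), monocyte markers with the mean of probe sets (0.0967) and FOXO targets without all arrays of replicate 2 (0.0752). Adjusted over the list alone, 0 members of these lists passed. ATF4 and amino acid response genes had a median of -0.07 and passed with the block (camera adjusted p = 0.0456, against 0.101 without it, and adjusted p = 0.538 with an estimated correlation) but not with the R mark as a term (adjusted p = 0.0587).

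The remaining lists did not pass for PD325901. Medians were -0.00 for immediate early genes, -0.04 for RAS, RAF, MEK and ERK components, -0.06 for PI3K, AKT and mTOR components, -0.01 for BCL2 family genes, 0.00 for myeloma oncogenes and surface receptors, -0.01 for NF-kB targets, -0.01 for adhesion genes, -0.07 for cholesterol synthesis, -0.06 for glycolysis and hypoxia, -0.01 for oxidative phosphorylation, 0.00 for lysosome and autophagy, -0.05 for the proteasome and -0.07 for interferon response genes. Median and mean differed in sign for B cell genes (0.01 and -0.02), cyclin D and CDK inhibitor genes (-0.05 and 0.07), p53 targets (-0.02 and 0.06), IL6-JAK-STAT3 genes (0.01 and -0.02), and receptor tyrosine kinases (0.02 and -0.02). T and NK (-0.00, with a mean of 0.01), fibroblast (0.02), erythroid (0.07) and endothelial markers (0.01) and tissue-restricted genes (0.02) stayed near 0. ARAF (-0.04), MAP2K1 (-0.13), MAP2K2 (-0.05) and MYC (0.11) did not pass.

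Comparing the inhibitors directly asks where inhibition of Raf and of MEK differed. With SB590885, 17 of 42 histone genes, 4 of 18 ERK feedback genes (with 1 lower), 10 of 29 amino acid response genes (with 1 lower) and 3 of 24 cholesterol synthesis genes were higher. The 3 cholesterol synthesis genes lost their calls without SB590885 replicate 1 or 2. Lower with SB590885 were 6 of 23 plasma cell genes and 5 of 27 unfolded protein response genes (with 1 higher). These lists passed camera at the preset correlation and none did with an estimated correlation (adjusted p = 0.177 for plasma cell genes to adjusted p = 0.429 for unfolded protein response genes). DUSP6 was at 8.64 ± 0.17 with SB590885 against 6.97 ± 0.25, a difference whose size is not taken as exact because the lower value is near the median of all probe sets of 6.92 (n = 4 each, adjusted p = 0.000192). DCLK1 was at 9.94 ± 0.08 against 11.75 ± 0.25, lower with SB590885 at 0.285 of the PD325901 level (adjusted p = 9.85e-05).

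Against PD325901, 389 genes were higher and 169 lower with SB590885, 558 in all. With the block 3582 passed (2449 higher, 1133 lower), all 558 among them in the same direction, and with the R mark as a term 3187. Arrays without the mark gave 2358 (1261 higher, 1097 lower) and those with it 1770 (1448 and 322), and all 558 had 1 sign in both sets. Quantile normalisation gave 877 higher and 679 lower. Without SB590885 replicate 2 the count was 281, without SB590885 replicate 1 it was 305, and without PD325901 replicate 4 it was 370. Changes of at least 1 on the log2 scale were 26 higher and 11 lower.

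ERK feedback regulators were higher with SB590885 by a median of 0.22, with 4 higher, 1 lower and 13 not passing (8 and 1 adjusted over the list alone, 9 and 2 with the block; camera adjusted p = 0.000262, and adjusted p = 0.177 with an estimated correlation). DUSP5, a nuclear ERK phosphatase, was higher by 1.51, and SPRED2 stood at 8.41 ± 0.13 against 6.93 ± 0.07, where the size is again not exact. ERK pathway output had 2 higher, DUSP6, which is also in the feedback list, and ETV5 (0.61), and 8 not passing (3 higher adjusted over the list alone and with the block; camera adjusted p = 0.0055, and adjusted p = 0.177 with an estimated correlation). DUSP4 differed by 0.53 (adjusted p = 0.114, and 0.0105 with the block). H2BC12 was higher by 2.41, H2AC6 by 2.25, H2BC6 by 1.99, IGLC1 by 2.03 and RAB11FIP1, of recycling endosomes, by 1.66. Of the 42 histone genes 17 were higher and 0 lower, and against DMSO PD325901 changed 0 of them by limma (median -0.00, 0 also unadjusted and with the block).

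Amino acid response genes were higher by a median of 0.43, with 10 higher, 1 lower and 18 not passing (19 and 1 adjusted over the list alone, 22 and 1 with the block; camera adjusted p = 5.26e-15, and adjusted p = 0.177 with an estimated correlation). TRIB3, a pseudokinase induced by ATF4, was higher by 0.92, SESN2 by 1.04 and CHAC1 by 0.54. FOXO targets had 4 higher and 16 not passing (8 adjusted over the list alone; 11 higher and 1 lower with the block; camera adjusted p = 0.000159, and adjusted p = 0.375 with an estimated correlation), with TSC22D3 at 1.51. The other higher members, CCNG2, BCL6 and KLF2, lost their calls without SB590885 replicate 2 (adjusted p = 0.112, 0.108 and 0.0937). Cholesterol synthesis genes had 3 higher and 21 not passing (6 adjusted over the list alone, 11 with the block; camera adjusted p = 2.13e-08, and adjusted p = 0.236 with an estimated correlation). All 3, IDI1, FASN and ELOVL6, lost the call without SB590885 replicate 1 (adjusted p = 0.0534, 0.135 and 0.0819) or 2 (adjusted p = 0.0626, 0.139 and 0.0823). NF-kB targets had 3 higher and 23 not passing (10 adjusted over the list alone, 12 with the block; camera adjusted p = 0.000184, and adjusted p = 0.177 with an estimated correlation). Of these, RELB (adjusted p = 0.0546) and WTAP (adjusted p = 0.0768) lost their calls without SB590885 replicate 1. Without SB590885 replicate 2, REL (adjusted p = 0.0723) and WTAP (adjusted p = 0.0850) did. Immediate early genes had 1 higher and 33 not passing (3 adjusted over the list alone; 14 higher and 2 lower with the block; camera adjusted p = 0.00191, and adjusted p = 0.467 with an estimated correlation). That gene, KLF2, lost its call when any of 8 arrays was left out (highest adjusted p = 0.0957).

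DNA replication genes were higher by a median of 0.17, with 1 higher and 40 not passing (7 adjusted over the list alone; 24 higher and 1 lower with the block; camera adjusted p = 4.73e-06, and adjusted p = 0.541 with an estimated correlation). The higher gene, TK1, lost its call when any of 6 arrays was left out (highest adjusted p = 0.103). Mitosis genes had 3 higher and 37 not passing (5 adjusted over the list alone; 15 higher and 1 lower with the block; camera adjusted p = 0.00422, and adjusted p = 0.622 with an estimated correlation), with CDC25C, the phosphatase of mitotic entry, at 0.44 and CENPF at 0.41, neither of which passed with quantile normalisation (adjusted p = 0.101 and 0.0529), nor CENPF with the mean of its probe sets (adjusted p = 0.177). This list lost its call without PD325901 replicate 3 (adjusted p = 0.445) or 4 (adjusted p = 0.0520), or with low genes left out (adjusted p = 0.0555).

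Plasma cell identity genes were lower with SB590885 by a median of -0.31, with 6 lower and 17 not passing (10 adjusted over the list alone, 14 with the block; camera adjusted p = 8.67e-13, and adjusted p = 0.177 with an estimated correlation). SLAMF7 was lower at -1.01, CAV1 at -0.95, XBP1, the plasma cell transcription factor, at -0.78 and MZB1, an endoplasmic reticulum protein of antibody secretion, at -0.61. Unfolded protein response genes had 5 lower, 1 higher and 21 not passing (14 and 1 adjusted over the list alone, 19 and 3 with the block), a median of -0.31 (camera adjusted p = 3.69e-10, and adjusted p = 0.429 with an estimated correlation). PDIA3, a disulfide isomerase, stood at 0.501 of its PD325901 level and SDF2L1 at 0.646, and ERN1, which encodes the stress sensor IRE1, was 2.83-fold higher. RELN was lower at -1.36, SCN3A at -1.21, MLKL, which executes necroptosis, at -1.20, PTPRZ1 at -1.14 and EAF2 at -1.10.

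Ribosome biogenesis genes were lower (median -0.12) with 0 of 35 passing over all genes or adjusted over the list alone, 9 lower unadjusted and 11 lower with the block (camera adjusted p = 0.000201, and adjusted p = 0.541 with an estimated correlation). Heat shock genes had 2 lower and 14 not passing (7 adjusted over the list alone, 9 with the block; camera adjusted p = 1.05e-06, and adjusted p = 0.177 with an estimated correlation), with FKBP4 at -0.47. HSPH1, also lower, lost its call when any of 8 arrays was left out (highest adjusted p = 0.118). The proteasome list (median -0.09, 0 of 22 passing and 0 unadjusted, 3 lower with the block, camera adjusted p = 0.0105, and adjusted p = 0.622 with an estimated correlation) lost its call without PD325901 replicate 1 (0.150) or 2 (0.405) or SB590885 replicate 3 (0.109), without all arrays of replicate 2 (0.387), or with the mean of probe sets (0.0706). T and NK markers (median -0.05, 1 lower and 19 not passing, 2 lower adjusted over the list alone, camera adjusted p = 0.00934, and adjusted p = 0.496 with an estimated correlation) lost theirs without SB590885 replicate 1 (0.0668) or PD325901 replicate 3 (0.0718). The interferon list (median -0.32, 0 of 37 passing, 2 lower unadjusted, 3 lower and 1 higher with the block, camera adjusted p = 0.00422, and adjusted p = 0.687 with an estimated correlation) lost its call, with the direction turned, without PD325901 replicate 2 (0.752).

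The other lists did not pass between the inhibitors. Medians were 0.05 for RAS, RAF, MEK and ERK components, 0.06 for BCL2 family genes, 0.06 for p53 targets, -0.06 for B cell genes, 0.03 for IL6-JAK-STAT3 genes, -0.04 for adhesion, 0.06 for lysosome and autophagy and -0.01 for receptor tyrosine kinases. PI3K, AKT and mTOR components (median 0.13) passed with the block (camera adjusted p = 0.019, against 0.0601 without it, and adjusted p = 0.347 with an estimated correlation) and with the R mark as a term (adjusted p = 0.0228). Myeloma oncogenes and surface receptors (median -0.03) passed with the block (camera adjusted p = 0.0471, against 0.0805, and adjusted p = 0.309 with an estimated correlation) but not with the R mark as a term (adjusted p = 0.0766). Median and mean differed in sign for cyclin D and CDK inhibitor genes (0.04 and -0.01), secreted cytokines (-0.03 and 0.06), glycolysis and hypoxia (0.02 and -0.02) and oxidative phosphorylation (-0.01 and 0.00). Monocyte (-0.01), fibroblast (-0.03), erythroid (-0.03) and endothelial markers (-0.02) and tissue-restricted genes (-0.01) stayed near 0. ARAF (0.08), MAP2K1 (0.12), MAP2K2 (0.14), ETV4 (0.06), SPRY2 (-0.07), SPRY4 (0.01), PHLDA1 (0.02), CCND1 (0.08), EPHA2 (-0.00) and EPHA4 (0.07) did not pass, and MYC, at -0.19, passed with the block (adjusted p = 0.0245) and with the R mark as a term (adjusted p = 0.0379), against 0.596 without them.

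Setting both inhibitors against DMSO asks which changes they shared. Both lowered 32 genes and raised 4, TP53INP1, SMIM14, DAPK1 and DNAJB2. With PD325901, TP53INP1 lost its call without any of 4 arrays (highest adjusted p = 0.0962), SMIM14 of 8 (0.114) and DAPK1 of 10 (0.133), and with centred arrays they did not pass (0.0568, 0.0794 and 0.0695). Shared falls included CCL2 (-2.00 with SB590885, -2.60 with PD325901), ETV5 (-1.21 and -1.82) and DUSP4 (-0.92 and -1.44). The sizes of the PD325901 falls of CCL2 and ETV5 are again not taken as exact. Both comparisons use the same DMSO arrays. Splitting these between the comparisons leaves fewer arrays to each and unbalances the replicate numbers. The mean number shared was then 9.5 (5 to 17), so the part of the overlap due to sharing was not separated. Of the 32 shared falls, 6 were deeper with PD325901 by the direct test (DUSP6, IL16, ETV5, PER2, FCMR and PYCARD) and 0 deeper with SB590885. With the block 606 fell and 106 rose with both, and 72 of the shared falls were deeper with PD325901 and 85 with SB590885. The shared 36 were 20 without DMSO replicate 1, 23 without SB590885 replicate 1 and 17 without DMSO replicate 2. Genes singled out here outside the naming rule were chosen after their values were seen.

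Moving in opposite directions were 2 genes, DCLK1 (-0.82 with SB590885, 0.99 with PD325901) and SLC25A20, a mitochondrial carnitine carrier (-0.28 and 0.45). Independent calls would give 1.88 such genes, a rough guide because the comparisons share the DMSO arrays. Across the 19775 genes, which are not independent replicates, the log2 fold changes of the inhibitors correlated at r = 0.370 (rho = 0.383). Unchanged groups sharing the DMSO arrays gave r = 0.494 in simulation (0.384 to 0.559), so the correlation alone does not show a shared response. Covariance was 0.00832, against 0.00217 in simulation. It was 0.00724 (0.00529 to 0.00923) without shared arrays, 0.00192 (-0.0040 to 0.0055) with DMSO split between the comparisons and 0.00448 where each part held arrays with and without the R mark. Pairs without shared arrays gave r = 0.278 (0.251 to 0.317), and DMSO split between the comparisons gave a mean r of 0.0821 (-0.113 to 0.215), or 0.170 where each part held arrays with and without the R mark. Splitting DMSO sets different replicate numbers against each inhibitor, so values from the splits do not show the effect of sharing alone. Within replicate numbers r was 0.356, 0.324, 0.375 and 0.402.

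**Figure D4:**
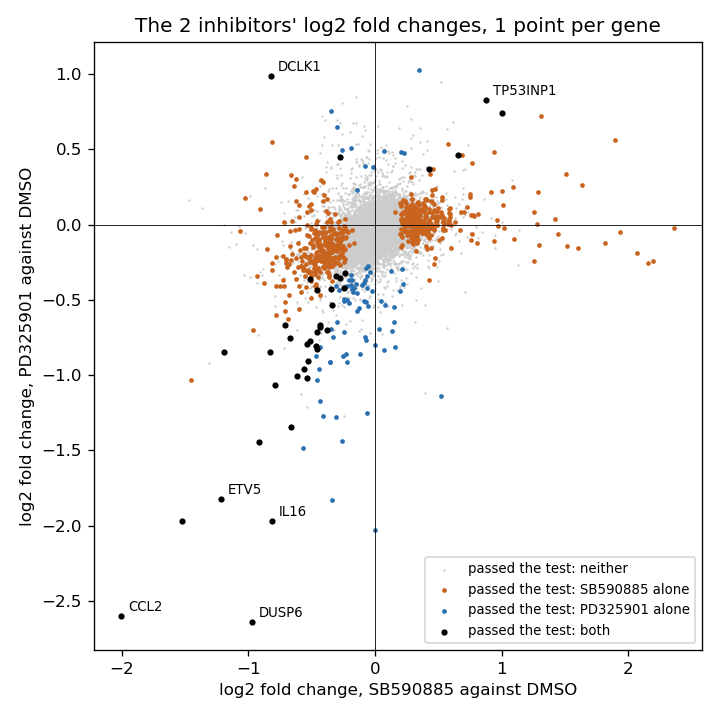
Log2 fold change of each of 19775 genes with SB590885 against DMSO (horizontal) and with PD325901 against DMSO (vertical), coloured by the comparisons in which the gene passed the test; both axes share the DMSO arrays. DUSP6 lies at -0.97 and -2.64, CCL2 at -2.00 and -2.60, and DCLK1 at -0.82 and 0.99.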

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

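Tests of the histone pattern, of the SB590885 replicate 2 array, of an effect of SB590885 on interferon genes, of a narrower scale and of 3' bias were chosen only after the result was seen, while those of other cell types and of other splits of the arrays were written before.

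One array stood far from the other 3 of its group in 21 of 382 groups of 4 values when the gap to the nearest array was divided by the group's range and set against Dixon's limit for 4 values. Chance gives about 1 in 20 such groups, and 7 of the 21 were at replicate 2. In DMSO this ratio was 0.887 for ATF3 and 0.912 for KLF2, both at replicate 2, 0.834 for SLA at replicate 4, 0.889 for RELB, 0.874 for FRZB and 0.843 for USP2 at replicate 1, 0.911 for PNOC at replicate 2 and 0.884 for PA2G4 at replicate 3. With PD325901 it was 0.839 for ETV5 and 0.937 for IL10 at replicate 1, 0.916 for ARAF at replicate 2, and 0.902 for FKBP4, 0.889 for MAP2K2 and 0.874 for CENPF at replicate 3. With SB590885 it was 0.831 for PHGDH and 0.900 for CDC25C, both at replicate 4. Among list medians it was 0.840 for ERK pathway output at PD325901 replicate 3, 0.891 for NF-kB targets at PD325901 replicate 1, 0.899 for IL6-JAK-STAT3 genes at DMSO replicate 2, and 0.913 and 0.895 for the interferon response at replicate 2 of DMSO and PD325901.

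Interferon response genes had a median of 11.2 and 11.1 at replicate 2 of DMSO and PD325901 and 8.57 at replicate 2 of SB590885. RNA of other cell types was argued against, since the highest median deviation of 5 marker lists on both arrays was -0.0037. An SB590885 replicate 2 array from another culture stays open: its lower correlation with arrays of its number was 0.628 (DMSO) and the higher 0.673 (PD325901), against 0.606 and 0.671 with those of number 1, and in a second test, chosen after the first was seen, the difference of replicates 2 and 1 correlated at -0.020 with that of PD325901, although without the same genes replicates 4 and 3 gave only 0.0698 and 0.104. Whether SB590885 lowers interferon genes cannot be told apart from this, because the median change over replicates 1, 3 and 4 was 0.0011 where the response was low, and -2.10 at replicate 2. An interferon response in 1 culture, lowered by SB590885, is a biological alternative that these arrays leave open.

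Arrays with the R mark stood apart from those without it in every group. Whether a narrower scale alone explains this was not settled. The PD325901 folds of the marked arrays had a slope of at least 1.06 on those of the unmarked arrays. A narrower scale alone would not give this, as it is above the ratio of the array SDs of 0.928. SB590885 slopes, 0.663 and 0.631, lay under that ratio. The slopes cover genes that passed with the block on these same arrays, which limits this test. The 3' bias of the RNA cannot be told apart from other differences, since the 3' minus 5' difference of GAPDH did not part the arrays (exact permutation test, two-sided p = 0.714) and that of ACTB did (p = 0.00216). Both tests permuted the arrays freely, without regard to the pairing. No biological explanation was tested, as the labels do not say what the mark means.

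Other splits of the 8 arrays tested each count of changed genes. For SB590885 against DMSO 1 of 35 splits, the real one, gave as many as 649, and the highest other gave 4. Free splits ignore the pairing and the R mark, so this count does not exclude chance. For PD325901 against DMSO 2 of 35 gave as many as the real split, so chance could not be excluded there either, with 117 genes against 6812 for the split by R mark. Between the inhibitors it was also 2 of 35, with 558 against 6503 for that same split, which points to a structure of the arrays. Over the 8 splits that part all 4 pairs, too few for a share under 0.05 in any comparison, the highest other count was 0, with and without the block, against 3742, 1610 and 3582 for the real splits with it.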

How the results depend on the processing

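Fits without replicate 2 and within each set by R mark were chosen after seeing the data, as was the correlation without shared arrays. Of values of called lists 753 stayed past or short of the threshold as before, 103 lost the call and 3 reversed. For named genes 2738 stayed, 297 lost and 6 gained the call and 37 reversed, none of the last past the threshold in the original fit. Of counts, correlation and overlap 119 stayed within the limit and 71 moved. Of 137 calls of named genes 90 held under every alternative run. The replicate block ended no call of a named gene. It changed the list calls given in the report and added many genes, such as those named under other observations.

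Genes changed with SB590885 against DMSO were 649 and became 432 with trend, 381 centred, 1632 with quantile normalisation, 1599 with array weights, 3742 with the replicate block, 3331 with the R mark, 3229 with the random block, 3571 averaged over second numbers, 78 without the arrays of number 2, 2637 without and 1066 with the mark, 32 at a log2 change of at least 1 and 157 at an adjusted p under 0.01. With 1 array left out they ranged from 245 to 691.

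For PD325901 against DMSO 117 became 190 over all probe sets, 351 with quantile normalisation, 194 with weights, 1610 with the block, 1289 with the R mark, 1147 with the random block, 1577 averaged, 63 without number 2, 186 without and 1079 with the mark, 21 at the log2 limit and 64 at 0.01, with 72 to 126 for 1 array left out. Between the inhibitors 558 became 854 over all probe sets, 307 centred, 1556 with quantile normalisation, 1352 with weights, 3582 with the block, 3187 with the R mark, 3115 with the random block, 3435 averaged, 180 without number 2, 2358 without and 1770 with the mark, 225 with 2 groups alone, 37 at the log2 limit and 180 at 0.01, with 281 to 509 for 1 array left out. Stricter limits lower counts by construction. Fewer arrays did not always lower them, as averaging gave 1577 against 117 for PD325901. Each average joined an array without the R mark and an array with it, so the mark's difference shared by the groups left the spread. The random block used a negative correlation, -0.562, between arrays of the same second number, which differ in the R mark. Otherwise the cause was not tested.

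Lists called, 16, 11 and 16, became 0, 2 and 0 with an estimated correlation and 10, 3 and 8 by fry. With the block as well as an estimated correlation they were 0, 1 and 0. The correlation of the inhibitors, 0.370, became 0.0821 with split controls and 0.278 without shared arrays, and ranged from 0.305 to 0.462 with 1 array left out. Split controls gave 0.170 where each part held arrays with and without the R mark. Such splits also unbalance the replicate numbers, so their values do not show the effect of sharing alone. The overlap of 36 became 9.5 with split controls, 712 with the block and 541 with the R mark, and ranged from 17 to 46.

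The interferon list reversed between the inhibitors without number 2 (adjusted p = 0.594) or PD325901 replicate 2 (adjusted p = 0.752), and for SB590885 against DMSO without DMSO replicate 2 (adjusted p = 0.896). The other reversed values were small changes of genes that did not pass in the original fit. Against DMSO with SB590885, the mean of probe sets gave PHLDA1 -0.014, CCND1 0.031 and EPHA4 0.0083, and quantile normalisation gave SPRY4 -0.00030, CCND1 0.033 and MAP2K1 0.0314. With PD325901, the mean gave PHLDA1 -0.072, ARAF 0.019 and MAP2K2 0.00084, quantile normalisation ARAF 0.024 and MAP2K2 0.034, and centring SPRY4 -0.0099. Between the inhibitors, quantile normalisation gave PHLDA1 -0.0064 and SPRY4 -0.00045. The cause was not tested.

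With 1 array left out, adjusted p of the interferon list ranged from 2.47e-05 to 0.896 for SB590885 against DMSO and from 0.00015 to 0.752 between the inhibitors. For SB590885 against DMSO, SPRY4 ranged from -0.024 to 0.054, CCND1 from -0.12 to 0.098, EPHA2 from -0.0053 to 0.082, EPHA4 from -0.049 to 0.033 and MAP2K1 from -0.059 to 0.034. For PD325901, SPRY2 ranged from -0.065 to 0.0016, SPRY4 from -0.058 to 0.047 and EPHA2 from -0.0023 to 0.080. Between the inhibitors, PHLDA1 ranged from -0.068 to 0.068, SPRY4 from -0.033 to 0.078, CCND1 from -0.00093 to 0.22 and EPHA2 from -0.051 to 0.043. Array minima were 5.85 to 6.01, and how far this limits falls of weakly expressed genes was not tested.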

Other observations

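The tests of the histone pattern in this part were chosen only after the result was seen.

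With the replicate block, 15 of 27 unfolded protein response genes rose with PD325901 and 0 fell. PDIA3, a disulfide isomerase, was higher by 0.70 (block adjusted p = 3.2e-06), CRELD2 by 0.59, DNAJB9 by 0.63, SEL1L by 0.45 and HSP90B1, the chaperone GRP94, by 0.42. These genes did not pass without the block and were chosen after their values were seen.

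With the block 130 genes moved in opposite directions, fewer than the 149.2 expected from independent calls. That number is a rough guide, since both comparisons share the DMSO arrays. Of the 130, 66 were higher with SB590885 and lower with PD325901. They included RAB11FIP1 (0.52 with SB590885, -1.14 with PD325901), DUSP5 (0.40 and -1.12), CEBPB (0.22 and -0.53), TRIB3 (0.39 and -0.53) and PSAT1, of serine synthesis (0.36 and -0.42).

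Histone genes rose with SB590885, and 2 explanations were tested. More cells in S phase was argued against only by the DNA replication and G1-S list, with a median of -0.013, 1 gene higher and 2 lower. With the block 3 were higher and 7 lower, and the share of cells in S phase was not measured. Probe sets shared by near-identical genes may explain part of the pattern, as the median of the 35 probe sets ending in _at alone was 0.14. Of these 35, 13 lay under the median of all probe sets, against 2 of the 13 shared ones, so this median does not separate sharing from weak signal. A second test, chosen after the first was seen, found 11 of these 35 higher past the threshold, which argues against sharing as the whole cause. A change in polyadenylated histone transcripts with SB590885 stays a hypothesis that was not tested.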
